A study of Homo sapiens with 8 samples.

How the data were processed

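Acetylation of lysine residue 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, had been profiled by chromatin immunoprecipitation and sequencing in MDA-MB-231, an established triple-negative breast cancer cell line, with and without ARID1A. ARID1A is a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex. The 8 libraries formed 4 groups of 2: control input, ARID1A knockout input, control immunoprecipitate and ARID1A knockout immunoprecipitate, as the titles and genotype labels gave them. Nothing in the labels stated whether replicates came from separate cultures or whether the knockout was a clone or a pool of cells. The labels named 2 antibodies: the sample characteristics gave an anti-H3K27ac antibody, whereas the extraction protocol, worded alike for every sample, named an antibody to H3K4me3. The catalogue number beside it, ab8895, is from general knowledge, and not from the sources used here, that of an antibody to H3K4me1. H3K27ac was taken as the mark, after the titles and characteristics, and the conflict was left open.

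The values used were 2 peak lists, 1 per genotype, each called on the immunoprecipitate against the input of that genotype. The group of each list was read from the genotype and library type in its name. Reads had been aligned with Bowtie2 2.3.5.1 to hg38 and peaks called with MACS2 2.2.6, per the submitters' processing notes. The options used, the read filters, the depth of each library and whether both replicates were pooled or 1 of them was used for a list were not given in the sources used here. Per the file headers, the authors listed for each peak its position, its width, the mean fragment pileup (a coverage signal), the −log10 p-value, the fold enrichment over the background estimated from the input (a ratio), and the −log10 q-value. All of these are the authors' values. The lowest −log10 q was 1.01 in the control list and 1.00 in the knockout list. Neither list had a summit column. Coordinates are 1-based, since the stated width equalled end minus start plus 1 for every peak.

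With 1 list per genotype there was 1 value per genotype and no spread between replicates. No p-value for the genotype could therefore be computed, no replicate could be left out, and a difference between the lists is a difference between these library sets. Fold enrichment was used only to describe, rank or filter peaks within a list, and folds were not compared between lists, except in the depth test of the closing section. Binomial intervals are exact (Clopper-Pearson) at 95% and cover counting error only.

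Peaks on chromosomes 1 to 22 and X were used. Peaks of both lists were merged into regions where they overlapped by at least 1 bp, and a region was shared, control-only or knockout-only. The overlaps of peaks expected by chance came from 100 shuffles of the peaks along their own chromosomes. A genotype-only region was called strong if its best peak lay in the upper 50% of its own list by fold enrichment and no peak of the other list lay within 1 kb. Overlap counts were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the same counts came from bedtools 2.31.1. Figures were drawn with matplotlib 3.10.9.

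Gene positions were those of RefSeq on GRCh38.p14, the same assembly as hg38, for 19974 protein-coding genes. The table used gave the start and end of each gene without strand or exons. The planned windows around transcription starts were therefore replaced by windows of 1 kb either side of both ends of each gene, called gene ends here, so a peak at a gene end can lie at the start or at the 3′ end of the gene. Of the genes with a peak at an end in either list, 18.8% had a peak at both ends. Regions away from gene ends were divided into those touching a gene body and those between genes, and exons and introns were not told apart. No genome sequence was used here, so a planned comparison of 23 sequence motifs, its alternatives and any matching on GC content were not run.

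The share of genotype-only regions at gene ends was placed among 10000 random sets of shared regions, drawn with replacement and matched on 10 bins of peak strength. For 18 gene lists (485 different symbols, all found in the gene table), the number of members with a knockout-only minus a control-only peak at an end was placed among 10000 random gene lists matched on 5 bins of strength. For distal regions, meaning regions outside gene ends with the nearest end of a protein-coding gene within 100 kb, the difference in percent was placed among 10000 random gene lists matched on the number of distal regions per gene. A list at or below percentile 1 or at or above percentile 99 was called apart, and 0.36 of 18 lists would be so by chance in each series. These percentiles describe the lists in hand and are not p-values for the genotype. The variance of the difference between knockout-only and control-only share over windows of 10 Mb with at least 20 regions was compared with 10000 permutations of the classes within 5 bins of strength. For broad domains, peaks away from gene ends were joined where they lay within 10 kb of each other, and the 20 domains with the longest summed peak length per list were taken.

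Genes and regions were named by a rule fixed before the data were examined, as were the gene lists. The rule took, per genotype, the 10 genes with the highest fold among strong genotype-only regions at gene ends and the 5 strong genotype-only regions with the highest fold away from gene ends. It also took up to 3 members per gene list and direction at gene ends, up to 3 members with the most genotype-only distal regions for lists called apart in the direction called, ARID1A, and the genes nearest to the 3 longest broad domains of each list. For replication and mitosis genes, 5 members tied behind RRM2 and all were named, which was decided after their values were seen. XIST and genes on the Y chromosome were left out. Alternatives were a stricter −log10 q or fold of at least 5, reciprocal overlap of 50%, a tolerance of 1 kb, equal numbers of peaks, other definitions of strong regions, windows of 2 kb, matching on 10 bins of peak width, a distal limit of 50 kb, windows of 5 Mb and joining within 5 kb. Further alternatives added after seeing the data are named where they are reported.

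The steps were tested on simulated data made from the control list. When 200 strong peaks were removed from a copy with shifted positions, 198 had no remaining peak within 1 kb, 198 strong control-only regions were called, and 0 false knockout-only regions were called. Of 100 random lists of 25 genes, 2 were called apart at gene ends, and all 100 lists with 5 planted knockout-only members were called. The background that the caller used for a peak was approximated as (pileup + 1) / fold − 1, which is not exact because the listed pileup is a mean. Its lowest level, taken at the lowest 0.1% of peaks, was 1.73 in the control list and 2.41 in the knockout list, a ratio of 1.39. This level moves with the depth and the fragment length used by the caller, and read numbers were not given in the sources used here. The authors' median pileup was likewise lower in the control list (22.7) than in the knockout list (32.0), as was the median approximated background (3.48 and 5.05).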

Results

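H3K27ac peaks were compared between control and ARID1A knockout MDA-MB-231 cells, to ask where this acetylation differed without ARID1A. Each genotype had 2 immunoprecipitated and 2 input libraries but a single peak list, so every value below is 1 value per genotype without replicate error, and no test of the genotype could be made. Fold enrichment is the authors' value for a peak over its own input-based background. Positions are on hg38. The mark is called H3K27ac after the titles and sample characteristics, whereas the extraction protocol named a different antibody, so the word acetylated rests on those labels.

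The ARID1A gene itself (chromosome 1, 26696015 to 26782104) was acetylated in both genotypes. Within 10 kb of the gene the control list had 7 peaks and the knockout list 6, and each of the 6 overlapped a control peak. In control cells a peak of 16.0 kb (26691721 to 26707680, fold 14.1) covered the lower-coordinate end of the gene. In knockout cells this stretch held 2 peaks, of 7.33 kb (26691390 to 26698722, fold 29.5) and 5.07 kb (26702397 to 26707470, fold 6.72). The 2 control peaks without a partner were weak, with folds of 2.60 and 2.55, at percentiles 4.97 and 3.51 of their list. A peak list does not show a small deletion or the loss of a protein, so these peaks do not check the genotype.

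**Figure D1:**
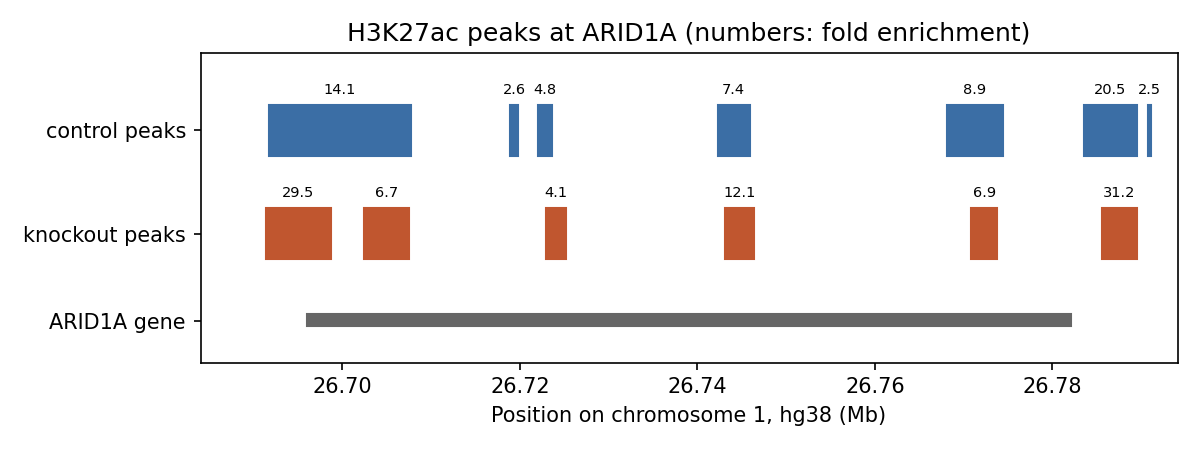
Peaks of each list within 10 kb of ARID1A, drawn to scale along chromosome 1 (hg38, Mb), with the authors' fold enrichment above each peak and the gene as a grey bar. The control list has 7 peaks and the knockout list 6, and the wide control peak at the lower-coordinate end of the gene faces 2 knockout peaks.

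The 2 genotypes had similar amounts of acetylated sequence, and the widest peaks were in the control list. Peak width also depends on where the caller joins or splits a stretch, and the background level differed between the lists. The control list held 39797 peaks covering 87.1 Mb and the knockout list 42552 peaks covering 89.7 Mb, a ratio of 1.07 in peak number. The median width was 1510 bp in control and 1527 bp in knockout. Peaks wider than 10 kb numbered 608 in control and 503 in knockout, those wider than 20 kb numbered 102 and 66, and those wider than 40 kb numbered 11 and 4. The widest control peak (76.2 kb, fold 10.6) lay in SMAD3, which encodes a transcription factor activated by TGF-beta receptors. The widest knockout peak, of 47.4 kb on chromosome 11 (122135741 to 122183178, fold 8.88), touched no protein-coding gene, and the next (46.1 kb) touched UGCG, which encodes glucosylceramide synthase. The median fold was 5.18 in the control list and 5.35 in the knockout list. Gene ends carried 28.9% of control peaks (95% interval 28.4 to 29.3) and 26.9% of knockout peaks (26.5 to 27.4).

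Most acetylated regions were common to both genotypes, and nearly every strong peak was. Of the control peaks, 82.0% (81.6 to 82.4) overlapped a knockout peak, against 6.30% on average after shuffling. Of the knockout peaks, 77.6% (77.2 to 78.0) overlapped a control peak, against 5.95% after shuffling. Merging gave 48662 regions, of which 31981 were shared, 7155 were control-only and 9526 were knockout-only. Sharing depended on strength: among the weakest 10% of peaks, 41.3% of control peaks (39.7 to 42.8) and 41.0% of knockout peaks (39.5 to 42.5) were shared. Among the strongest 10%, 99.9% were shared in each list, leaving 2 control peaks and 3 knockout peaks without a partner. With both lists restricted to a −log10 q of at least 5, control-only regions fell to 2719 and knockout-only regions to 7328. This cut was not alike for both lists, whose median −log10 q was 10.6 in control and 15.0 in knockout. It left 26745 control and 31598 knockout peaks, so the unequal fall does not compare the genotypes.

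**Figure D2:**
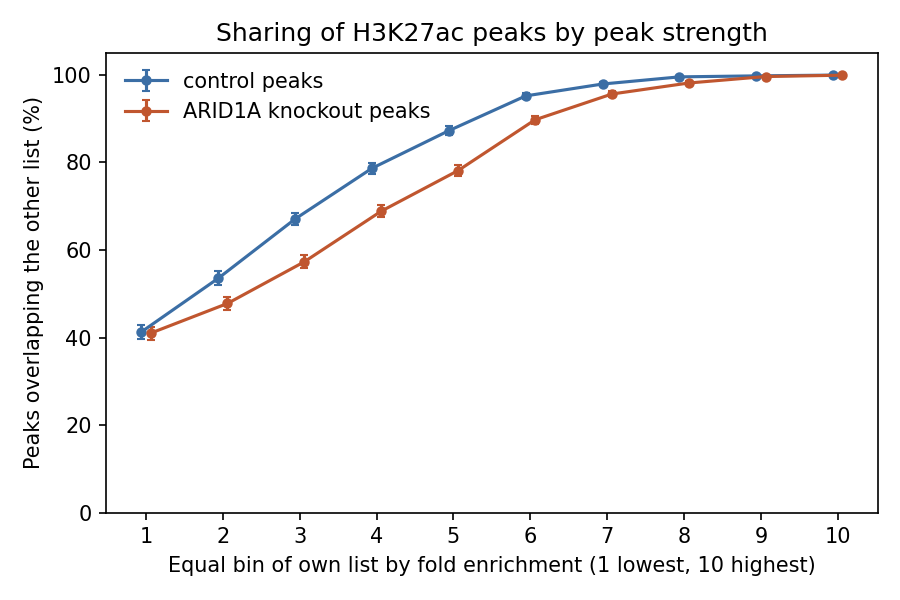
Percent of peaks that overlap a peak of the other list (vertical axis), for 10 equal bins of each list ranked by fold enrichment (horizontal axis, 1 lowest to 10 highest). Bars are exact binomial 95% intervals for counting error, and sharing climbs from 41.3% to 99.9% in control and from 41.0% to 99.9% in knockout.

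Strong genotype-only regions, with no peak of the other list within 1 kb, were 2.39 times as frequent in the knockout list (719) as in the control list (301). At gene ends, the control-only region with the highest fold (16.4; chromosome 11, 117815625 to 117819823) spanned an end of DSCAML1, a cell adhesion molecule of the immunoglobulin superfamily. It stopped short of the neighbouring end of FXYD2, a regulator of the sodium-potassium pump, and of the readthrough gene FXYD6-FXYD2, but lay within the 1 kb window there. The other control-only ends named by the rule were those of MYL5 (fold 10.6), C16orf86 and ENKD1 (1 region, 10.6), EMC10 and GARIN5A (1 region, 10.3), BEST1, a chloride channel gene (9.95), and MAJIN, a gene of meiotic telomere attachment (9.51). In the knockout list the ends with the highest fold were those of C1orf115 (12.3; chromosome 1, 220690298 to 220690851) and EPAS1 (10.9; chromosome 2, 46385229 to 46387370), which encodes the hypoxia-inducible factor HIF-2α. The EPAS1 region lay at the higher-coordinate end of the gene (46297407 to 46386697). Next came THOC3 (9.97), CELA1 (9.76), PYCARD, the inflammasome adaptor (9.53), GMFG (9.48), FXYD5 (8.91), the metallothionein gene MT1F (8.59), GRAMD2B (8.53) and FAM72B (8.35). The THOC3 and FAM72B regions were 266 and 253 bp wide, and FAM72B belongs to a family of near-identical copies, so reads there can be shared between copies. A peak of the other list lay within 5 kb of the MYL5, C16orf86 and ENKD1, BEST1, GMFG, FXYD5, MT1F, GRAMD2B and FAM72B regions.

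Away from gene ends, the strong knockout-only region with the highest fold (20.1; chromosome 7, 32904964 to 32906805) lay between genes, 12.8 kb from KBTBD2. The second was a single peak of 12.1 kb on chromosome 3 (104435166 to 104447242, fold 19.0), 920 kb from the nearest end of a protein-coding gene. The others lay 60.0 kb from AZIN1, an activator of polyamine synthesis (fold 16.5), on chromosome 14 at 97105295 to 97109637 (14.9), and 68.3 kb from CACNA2D3, a calcium channel subunit gene (14.7). In the control list the highest fold (15.1) was that of a region inside SHANK2, a synaptic scaffold gene (chromosome 11, 70933781 to 70936210). It was followed by regions on chromosome 13 (68256129 to 68257676, fold 13.1), on chromosome 12 (4164248 to 4165509, 11.7), inside FAM222A (11.7) and inside ZNF503 (11.3). When the strong class was restricted to the upper 25% of each list, 19 control-only and 47 knockout-only regions were left.

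Genotype-only acetylation lay mainly away from gene ends. Of the shared regions, 34.5% lay at a gene end, against 7.32% of control-only regions (6.73 to 7.95) and 4.77% of knockout-only regions (4.35 to 5.21). Shared regions of matched strength gave 9.03% and 9.36%, and both observed values lay below all 10000 matched sets. Shared regions were wider (median 2135 bp) than control-only (673 bp) and knockout-only regions (765 bp), and shared regions matched on width in place of strength gave 17.3% and 18.5%, again above both observed values in all sets. Among strong regions the values were 17.9% for control-only (matched 32.0%) and 8.48% for knockout-only (matched 26.2%), again below all matched sets. Between genes lay 30.7% of shared, 35.4% of control-only and 47.8% of knockout-only regions. With windows of 2 kb the control-only value was 10.5% against a matched 11.1%, at percentile 3.90 and so no longer apart.

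At the level of genes, the ends of housekeeping and cell-division genes were acetylated in both genotypes, and few genes of any list were acetylated in 1 genotype alone. All 30 housekeeping genes and all 31 replication and mitosis genes, such as MCM2, CCNB1 and TOP2A, had a peak at an end in both lists. So did 29 of 30 DNA repair genes, 25 of 27 SWI/SNF subunit genes, 25 of 27 YAP and TEAD target genes, 25 of 28 NF-kappaB and inflammatory genes, 22 of 23 antigen presentation and checkpoint genes, 21 of 24 p53 target and arrest genes and 17 of 19 AP-1 factor genes. The lists of genes of other cell types were mostly without a peak in either genotype: 16 of 24 blood cell genes and 12 of 20 neuron and hepatocyte genes. Basal identity genes had a peak in both for 13 of 24 members and in neither for 11. None of the 18 lists was called apart at gene ends, with percentiles from 5.91 for stem cell, Notch and Wnt genes to 94.2 for luminal and epithelial genes. No list differed by more than 2 members in either direction. The simulated lists had 5 planted members, so smaller shifts could go uncalled. With a −log10 q of at least 5, added after seeing the data, the stem cell, Notch and Wnt list turned from a difference of −2 members to 2 (percentile 97.7), the luminal and epithelial list came to percentile 41.2, and blood cell genes were called apart (0.45).

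The list members with a peak in the window at an end in 1 list alone numbered 14, and not all of them had genotype-only acetylation. Knockout-only members were ZEB2, a repressor of E-cadherin (fold 8.95), in the epithelial to mesenchymal transition list (24 of 34 in both), and ESR1, the oestrogen receptor gene (2.68), and ESRP1, an epithelial splicing regulator (3.52), in the luminal and epithelial list (17 of 30 in both). They also included the antiviral genes OAS1 and TRIM22 (2.54) in the interferon list (26 of 32 in both), CCL2, a monocyte-attracting chemokine (4.28), BMP2 (2.83) in the TGF-beta list (26 of 31 in both) and WNT7B (5.37). The last were ABCC2, a drug efflux transporter (14.2), in the transporter and metabolism list (23 of 26 in both), and STMN2, a neuronal gene (3.59). Control-only members were SOX2 (2.89), DLL1 (2.72) and TCF7 in the stem cell, Notch and Wnt list (18 of 28 in both) and FCGR3A (4.86) among blood cell genes. The peaks at ZEB2, ABCC2 and FCGR3A themselves overlapped a peak of the other list that stopped short of the window, so these regions were shared. At WNT7B a peak of the other list lay within 1 kb of the window, and CCL2 alone of the 14 stayed genotype-only under all 3 alternatives. The other 9 members had no peak left at an end in either list with a −log10 q of at least 5. Over all 19974 genes, 12204 had a peak at an end in both lists, 368 in control alone, 344 in knockout alone and 7058 in neither. With a −log10 q of at least 5 the order of the genotype-only counts turned, to 272 in control alone and 461 in knockout alone. That cut removed more control than knockout peaks, so the turn does not compare the genotypes.

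Around genes, distal acetylation of interferon response genes was more often knockout-only and that of replication and mitosis genes more often control-only. Of 44 distal regions of the interferon list, 15 were knockout-only (34.1%) and 2 control-only (4.55%), at percentile 99.3 of matched random lists. The 15 regions belonged to 12 members, with 3 at IRF1, a transcription factor of the interferon response, and 2 at GBP1, an interferon-induced GTPase. Of 42 distal regions of the replication and mitosis list, 19 were control-only (45.2%) and 6 knockout-only (14.3%), at percentile 0.315. RRM2, a ribonucleotide reductase subunit gene, had 3 control-only regions, and MCM5, CCND1, CDK1, CDC25A and TOP2A had 2 each. The other 16 lists were not called apart. Among them, blood cell genes had 9 knockout-only and 2 control-only regions of 21 (percentile 96.0), and NF-kappaB and inflammatory genes had 23 and 5 of 76 (97.3). Over all genes, 22.6% of distal regions were knockout-only and 18.7% control-only. The random lists were not matched on peak strength or gene density. They were also not matched on how close members lie to each other, and some interferon members, such as IFIT2 and IFIT3, are neighbours. Away from gene ends, control-only regions had on average 10.7 protein-coding genes within 500 kb and knockout-only regions 7.87. Gene density was therefore not separated from these calls. With strong genotype-only regions alone, neither call held: the interferon list had a difference of 0 percentage points (percentile 36.95) and the replication and mitosis list came to percentile 6.29, whereas blood cell genes came to percentile 99.1.

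**Figure D3:**
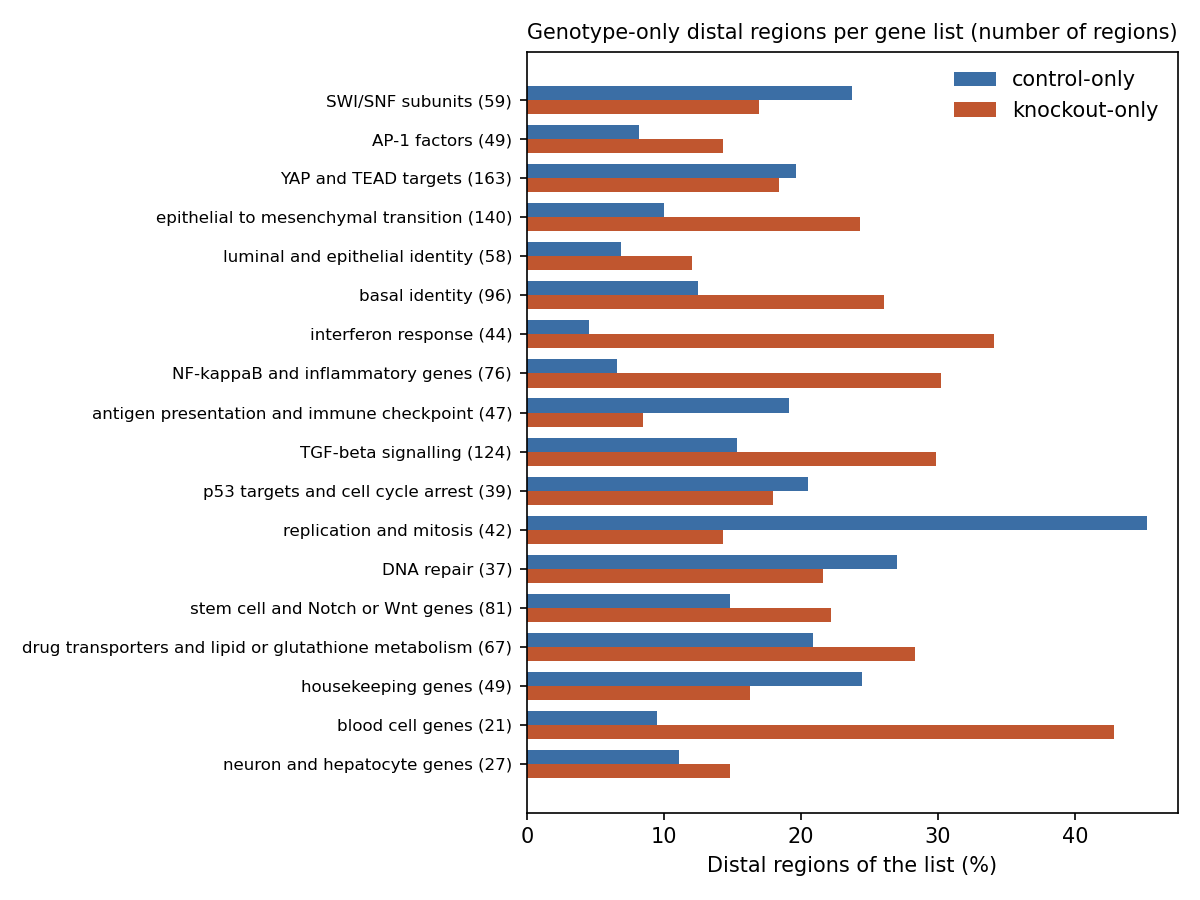
Percent of the distal regions of each gene list that were control-only or knockout-only, with the number of distal regions of the list in brackets. Bars start at 0 and have no error bars, since there is 1 value per list; interferon response genes (4.55% control-only, 34.1% knockout-only) and replication and mitosis genes (45.2% and 14.3%) were the lists called apart.

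Knockout-only regions were unevenly spread over the genome. Chromosome 13 had the highest share, with 29.1% of its regions knockout-only (26.7 to 31.7) and 12.1% control-only. It was followed by chromosome 21 (25.9%), chromosome 4 (25.2%) and chromosome 18 (25.1%). Chromosome 19, on which 45.5% of regions lay at gene ends, had the lowest share at 11.2% (9.81 to 12.6), with 13.6% control-only. On 4 of the 23 chromosomes (9, 17, 19 and 22) the control-only share was the higher, with the widest gap on chromosome 17, where 17.5% of regions were control-only. Over 300 windows of 10 Mb, the variance of the difference between both shares was 4.26 times the mean of permutations, and 0 of 10000 permutations reached it. With permutations made also within bins of gene density the ratio was 2.44, again reached by 0 of 10000. The permutations moved regions singly, whereas neighbouring regions could share a class, as the 10 knockout-only regions in TCF4 did. Such runs raise both ratios, so this comparison cannot tell them from a pattern on the scale of 10 Mb.

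**Figure D4:**
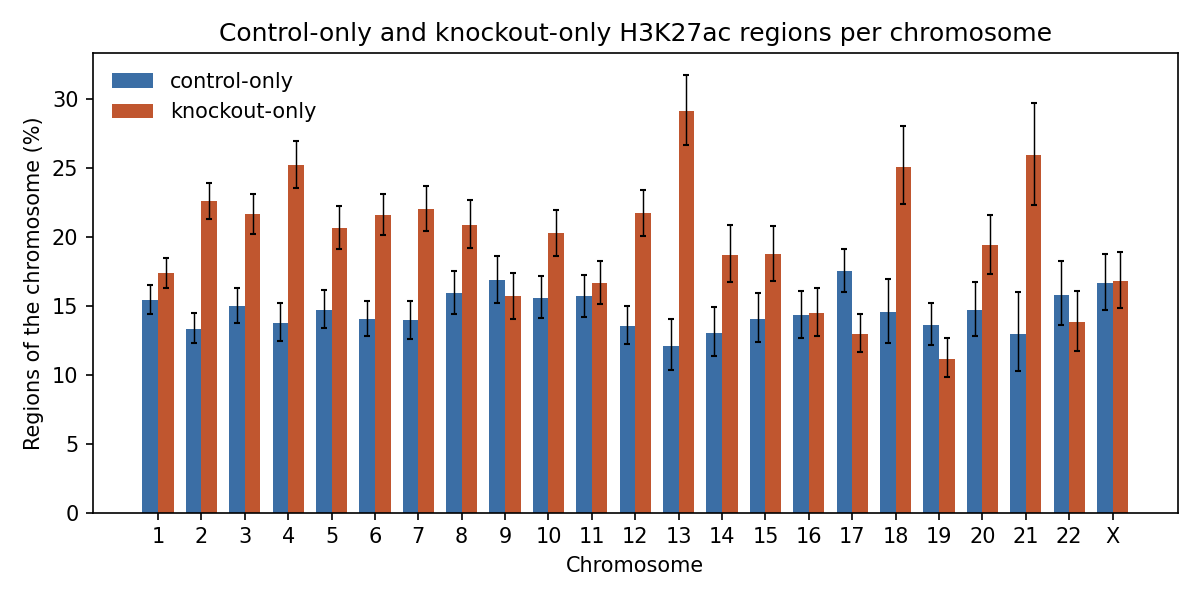
Percent of the regions of each chromosome (horizontal axis) that were control-only or knockout-only (vertical axis), with exact binomial 95% intervals for counting error as bars. Chromosome 13 has the highest knockout-only share (29.1%) and chromosome 19 the lowest (11.2%).

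The longest acetylated domains away from gene ends included one in SMAD3 in both genotypes, and the longest of control cells lay beside MYC. In control cells the longest, with 191 kb of summed peak length in 17 peaks, lay beyond this proto-oncogene, with its near edge 50.8 kb from the gene (chromosome 8, 127793779 to 128037170), and knockout peaks covered 57.6% of that length. The next were in SMAD3 (90.5 kb, 85.3% covered) and near KLF14, though 141 kb from that gene (78.2 kb, 74.9% covered). In knockout cells the longest were in SMAD3 (72.1 kb, 95.6% covered by control peaks), near MRPL14 (66.2 kb, 68.3%) and near BLID (65.7 kb, 96.0%). The MYC domain appeared in the knockout list as separate domains, of which those of 48.3 and 47.9 kb were among its 20 longest. All 20 of the longest domains of each list overlapped a peak of the other, with a median of 78.1% of control domain length and 95.1% of knockout domain length covered. The lowest coverage was 55.5% for a control domain and 31.3% for a knockout domain, which touched NRP1. Among 794 shared regions wider than 10 kb, control peaks covered more sequence in 481 and knockout peaks in 313. These regions held 1001 control and 1230 knockout peaks, so peak widths depended partly on how stretches were split. Over all 31981 shared regions, control peaks were longer in 15773 and knockout peaks in 16186, while the sequence covered was 81.0 Mb in control and 80.6 Mb in knockout.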

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

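The tests on depth, GC content and copy number were chosen after the patterns had been seen, whereas the test on gene density was set before its result was known, and the comparison with shared regions of matched strength was planned but read as a test of weaker peaks after its result.

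A signal lay outside the main measurement: the control list held 6 peaks and the knockout list 8 on 4 sequences outside the assembled chromosomes, which none of the comparisons used. All 6 control peaks had a knockout counterpart at nearly the same place.

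The first pattern is the excess of strong knockout-only regions (719 against 301). When the pileup and background of the knockout peaks were scaled by 0.719 to the background level of the control list, 656 of the 719 still reached the median fold of the control list. That scaling lowered no fold by more than 9.48%, so the test had little room to come out otherwise, and read numbers were not given in the sources used here. An effect of depth or enrichment of the libraries on this excess therefore cannot be told apart from loss of ARID1A, for which there was 1 knockout list and no spread. With equal numbers of peaks, an alternative added after seeing the data, the counts were 341 and 544.

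The second pattern is that genotype-only regions lay away from gene ends. Control-only regions differed by −1.71 and knockout-only regions by −4.60 percentage points from shared regions of matched strength, below all 10000 matched sets. A lower fold in the own list is therefore not the whole cause. Shared regions, however, also had a peak in the other list, so at equal fold their signal may be higher. Strength and width were matched separately and not together. Whether weaker signal is the whole cause therefore cannot be decided. With 2 kb windows the control-only value was no longer apart. A GC difference between the libraries cannot be told apart from loss of ARID1A for either class, because matching on GC was not run, and −1.71 and −4.60 are the values that define the pattern. Loss of ARID1A stays open and untested.

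The third pattern is the uneven share of knockout-only regions along the genome. The background of the knockout list relative to the control list, each divided by its own median, was highest on chromosome 13 (log2 difference 0.49, above 0 in 10 of 10 windows of 10 Mb). Over 298 windows, however, this relative background and the difference in share had a partial Spearman correlation of 0.114 with gene density held fixed. Its 95% bootstrap interval was −0.0119 to 0.233. Without gene density held fixed, the Spearman correlation was 0.155 and the Pearson correlation 0.243. These low values argue against copy number as the main cause of the order of windows over the genome. The quartiles of the log2 difference were −0.097 and 0.039, so many windows were ranked on small differences. The test therefore cannot decide on an effect of copy number limited to segments with larger differences, such as chromosome 13. In some such windows the share went with the background. The window from 60 Mb of chromosome 7 had a log2 difference of 1.06 and a difference in share of 31.0 percentage points. In others it went against the background, as in that from 0 Mb of chromosome 3, with −0.52 and 14.9. The Spearman correlation of the difference in share with gene density was −0.497, stronger than that with the relative background. Permuting within bins of density lowered the variance ratio from 4.26 to 2.44, still above every permutation. Gene density thus accounted for part of the pattern. The permutations moved regions singly, so whether the rest goes beyond runs of neighbouring regions of the same class cannot be decided. A GC difference between the libraries also stays open for this pattern, because no genome sequence was used. Loss of ARID1A was not tested here either, and leaving out chromosome 13 gave a ratio of 4.19.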

How the results depend on the processing

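The alternatives on regions under 500 bp, equal numbers of peaks for strong regions, −log10 q for gene lists at gene ends, gene-end permutations and leaving out chromosome 13 were added after seeing the data, as was the 5 kb distance for the share at gene ends. No paired analysis was possible because each genotype had a single peak list, so replicate numbers could not enter; leaving out a replicate and the motif alternatives were not run for the same want of replicate lists and of a genome sequence. Of 59 alternative values of the main results, 38 stayed the same, 20 moved and 1 lost its call. Counts of peaks, regions and genes were called the same up to a factor of 1.5, so this tally does not show that their order held. Genes with a peak at an end in 1 list alone numbered 368 in control and 344 in knockout. At the stricter q they came to 272 and 461, each called the same. Strong knockout-only regions outnumbered strong control-only regions under every alternative tried. With a fold of at least 5 the lists held 20572 control and 22592 knockout peaks, fewer by construction, and the ratio was 1.10; with −log10 q of at least 5 it was 1.18. Shared control peaks came to 65.8% with 50% reciprocal overlap, 82.4% with a 1 kb tolerance, 89.8% with −log10 q of at least 5 and 79.6% with equal numbers. Shared knockout peaks came to 61.5% with reciprocal overlap, 76.8% with the stricter q and 80.2% with equal numbers. Without a reciprocal match were 13624 control and 16379 knockout peaks; 2719 control-only regions remained at the stricter q. The upper 25% left 19 control-only and 47 knockout-only strong regions. Ranked by −log10 q, 36.5% of the weakest 10% of control peaks and 37.4% of knockout peaks were shared. Windows of 2 kb gave 10.5% of control-only regions at gene ends, at percentile 3.90; the cause was not tested. At gene ends 1 list (blood cell genes, percentile 0.45) was apart with −log10 q of at least 5, and 1 distal list (blood cell genes, percentile 99.1) was apart with strong regions alone, where both lists of the main setting lost their calls, interferon genes at percentile 36.95 with a difference of 0 and replication and mitosis genes at 6.29; the causes were not tested. Of 72 values of single lists, 68 stayed on their side of the threshold. The unknown depth limits what an absent weak peak can show.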

Other observations

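All values in this part were chosen after the data had been seen, and none tests the genotype.

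Several genes had runs of genotype-only acetylation. TCF4, a basic helix-loop-helix transcription factor gene on chromosome 18 (55222185 to 55635957), had 10 knockout-only regions, 5 of them strong (folds 5.48 to 10.4), and no shared or control-only region. In 5 of 1000 draws of strong shared regions away from gene ends, a gene held as many. CDH8, a cadherin gene, had 6 knockout-only regions and no other, 4 of them strong. FOXP1, CSGALNACT1 and SAMSN1 had 3 strong knockout-only regions each, which was the median of the highest count per draw, and FOXP1 also had 12 shared and 3 control-only regions. In the control list TNS1, which encodes the focal adhesion protein tensin, had 7 control-only regions, 3 of them strong, beside 1 shared, and 47 of 1000 draws held a gene with as many strong regions. Near ADAMTS15, a secreted protease gene, 4 strong knockout-only regions lay within 100 kb, a count that 42 of 1000 draws reached. For strong control-only regions within 100 kb the highest count per gene was 2, which 987 of 1000 draws reached. Knockout-only regions wider than 8 kb numbered 11, and control-only regions of that width 0. The widest control-only region was 7.77 kb, just under this limit, so that 0 rests on the limit chosen. The widest knockout-only regions were a peak of 21.3 kb in FMN2 (fold 12.3), a peak of 16.0 kb on chromosome 19 (23546212 to 23562204, fold 13.1) and a peak of 14.4 kb in TCF4 (fold 10.4).

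Members of 1 gene list could lie on opposite sides, as TGF-beta pathway genes did. The inhibitory SMAD genes SMAD6 and SMAD7 had 7 and 5 knockout-only distal regions and 0 control-only, whereas SMAD3 had 5 control-only and 0 knockout-only and SKI had 6 and 1. CRIM1 had 8 control-only distal regions and LOXL2, a collagen cross-linking enzyme gene, had 7, both with 0 knockout-only, while CAV2 had 6 and CCL20, a chemokine gene, had 5 knockout-only with 0 control-only. Regions away from gene ends had on average 10.7 protein-coding genes within 500 kb when control-only (strength-matched shared regions 9.35) and 7.87 when knockout-only (matched 9.76).

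No peak of either list lay between positions 20733256 and 24912632 of chromosome 9, a gap of 4179 kb with 24 protein-coding genes that include MTAP and CDKN2A, a tumour suppressor locus known to be deleted in MDA-MB-231. Of 48639 gaps between regions, 13 were as long. The relative background was also uneven outside chromosome 13: on chromosome 3 the log2 difference of knockout against control was −0.28, below 0 in 15 of 19 windows. Values for a whole chromosome can hide segments of opposite sign. On chromosome 10 the log2 difference was 0.025, with 0.50 in the window from 0 Mb and −0.34 in that from 50 Mb. The knockout-only minus control-only share in those windows was 16.7 and −19.8 percentage points. The windows from 60 Mb of chromosome 7 and from 50 Mb of chromosome 19 had log2 differences of 1.06 and −0.59. Their differences in share were 31.0 and −0.82 percentage points. Copy number itself was not measured.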
